A study of Tremella fuciformis and Annulohypoxylon stygium and Tremella fuciformis
Annulohypoxylon stygium with 5 samples.

How the data were processed

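The data were transcriptomes of mycelia of the white jelly fungus Tremella fuciformis and of Annulohypoxylon stygium, the ascomycete it is grown with. There were 5 libraries, 1 for each condition. T. fuciformis was sampled alone at 2 weeks and 1 week after interaction with A. stygium. A. stygium was sampled alone at 1 week and 1 week after interaction with T. fuciformis. The dual library held mycelia of both fungi 1 week after they had met. Each library was placed in its group from its source name. Per the labels' protocols, RNA was extracted with Trizol reagent and libraries were made with standard Illumina protocols, and per the series' design text they were sequenced on an Illumina instrument.

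The authors deposited 1 table of 42507 de novo assembled sequences (unigenes), with an FPKM value (fragments per kilobase of sequence, scaled to library size) for each unigene in each library and with database hits for each unigene. Per the file headers these hits came from Nr, SwissProt and other databases. The assembler, the aligner and the counting tool are not given in the sources used here, nor is whether each library pooled several cultures. The FPKM values were used as deposited. The table held 0 further columns of values per library. The names show 23751 contigs grouped in 8267 assembly clusters and 18756 single unigenes. Contigs of 1 cluster are taken to be related sequences between which reads can be split, but their similarity was not measured. Some clusters join contigs with different descriptions or contigs assigned to different fungi, and only contigs with the same assignment were summed.

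The description of a unigene was that of its Nr hit, unless that hit was hypothetical, uncharacterized, predicted, unnamed or unknown, in which case the SwissProt hit was used if its e-value was at most 1e-20. This use of SwissProt and its limit were chosen after the table was seen. Of 31124 unigenes with an Nr hit, many had no informative name, and 18382 unigenes in all had a usable description, 13254 from Nr and 5128 from SwissProt. Descriptions are names of the nearest hit and not tested functions. No genome was used here, so unigenes carry no chromosome positions.

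A unigene was assigned to a fungus when its highest FPKM in that fungus's 2 single-fungus libraries was at least 1 and at least 10 times its highest FPKM in those of the other fungus. The dual library took no part in this. Unigenes that reached 1 FPKM but not the 10-fold ratio were called shared, and those below 1 FPKM in all 4 single-fungus libraries were called low. For each comparison FPKM values were rescaled so that the unigenes of the fungus summed to 1e+06 in each library, because the dual library divides its reads between 2 fungi. The ratio was log2((interacting + 1)/(alone + 1)) of the rescaled values, over unigenes with at least 1 FPKM in at least 1 of the 2 libraries. The pseudocount of 1 understates the change of unigenes with low values.

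With 1 library per group no test was possible, and no p-value is given. Values, ratios and the number of unigenes with a log2 ratio of at least 2 (4-fold higher) or at most -2 (4-fold lower) are reported, and they describe these libraries and not the conditions. A total of 24 gene lists was fixed as search words in the descriptions. They cover hydrophobins, breakdown of cellulose, of hemicellulose and pectin, and of chitin and beta-1,3-glucan, lignin-modifying oxidases, synthesis of the cell wall and of capsule and nucleotide sugars, secreted-type proteases, transporters of sugars and of amino acids, peptides and ammonium, drug efflux transporters, and synthesis of polyketides, nonribosomal peptides and terpenes. They also cover cytochrome P450, oxidative stress defence, heat shock proteins, cytosolic ribosomal proteins, mitochondrial respiration, glycolysis, glyoxylate cycle and beta-oxidation, mating and pheromones, cell cycle and DNA replication, lectins and adhesins, iron and siderophores, and transposable elements and viruses. For a list of at least 5 members, the median log2 ratio was set against the medians of 10000 random lists of the same size matched on mean expression in 20 bins. Its percentile among them is a description and not a p-value, since members of 1 list share clusters and regulation. The search words are broad, so the ribosomal list also holds some mitochondrial ribosomal proteins and the cellulose list some beta-1,3-glucosidases that the chitin and glucan list holds too.

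Named unigenes followed a fixed rule. In each comparison they were the 10 with the largest increase and the 10 with the largest decrease of the log2 ratio among described unigenes with at least 10 FPKM in 1 of the 2 libraries, 1 per description. The rule also took, from each list, the member with the highest mean FPKM and the member of at least 10 FPKM with the largest ratio, and the text leaves out some of these. The lists, the rule, the comparisons and their alternatives were fixed before the data were examined.

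The depth is not stated, but low FPKM values are multiples of the value of 1 read. In 1292 unigenes these steps gave a median of 0.05 FPKM per read, with quartiles of 0.03 and 0.08. The same steps gave a relative depth between 0.971 and 1.07 of that of A. stygium alone. Only unigenes with nearly equal low values in both libraries entered this estimate. It therefore had to lie near 1 and cannot show that the depths were equal. At the median step a unigene at 10 FPKM rests on about 200 reads, with a counting error of 7.07%. A unigene at 1 FPKM rests on about 20 reads, with one of 22.4%. These errors cover counting only and leave out the spread between cultures, which the design did not measure. Listed zeros come without counts, so no fold is given against a library at 0.

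The procedure was tested on data simulated from the library grown alone, with counting noise only. There 200 unigenes with at least 10 FPKM were changed 8-fold. For T. fuciformis after interaction it recovered 100% of these among 13957 unigenes, and in the dual library 99.5% among 13736. For A. stygium it recovered 100% among 16987 unigenes after interaction and 100% among 16687 in the dual library. In each of the 4 simulations 0 unchanged unigenes passed 4-fold. These outcomes follow from such settings, and the spread between cultures was left out. They do not show that the observed 4-fold counts exceed noise. The simulated unchanged groups with more than counting noise, and the summed levels of lists, were added after the data were seen. Of 200 random lists, 7% fell outside the band from percentile 2.5 to 97.5. Alternatives were a pseudocount of 0.1 or 5, no filter, a filter at 10 FPKM, FPKM without rescaling, scaling by the median ratio, assignment at 100-fold or 3-fold or on the libraries grown alone, and a 2-fold threshold. Summing the contigs of a cluster, and the lists without rescaling, were alternatives added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots matplotlib 3.10.9.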

Results

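Transcript levels were measured in mycelia of T. fuciformis and A. stygium, each grown alone and each after contact with the other, and in mixed mycelia of both. Summed FPKM was 641184 in T. fuciformis alone, 657997 in T. fuciformis after interaction, 599253 in the dual library, 545561 in A. stygium after interaction and 524250 in A. stygium alone. Each condition had 1 library, so no difference described here could be set against a spread between replicates. The cultures grown alone were 2 weeks old for T. fuciformis and 1 week old for A. stygium. The interacting mycelia were sampled 1 week after contact and their total age is not given in the sources used here, so culture age and interaction cannot be separated in either fungus.

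The first question was how much of each library came from each fungus. T. fuciformis was assigned 15354 unigenes and A. stygium 18667, while 516 were shared and 7970 were low. The nearest Nr hit lay in a genus of Tremellomycetes for 85.8% of T. fuciformis unigenes with a hit and for 0.481% of A. stygium unigenes. Hits in genera of Xylariales, the order of A. stygium, made up 0.248% and 71.1%. Unigenes of T. fuciformis held 99.2% of the FPKM in each of its own libraries, and unigenes of A. stygium held 99.0% after interaction and 98.9% alone. The dual library held 36.4% T. fuciformis and 59.0% A. stygium. The libraries sampled after interaction contained little of the partner, 0.0626% A. stygium in T. fuciformis and 0.0670% T. fuciformis in A. stygium. The libraries grown alone held 0.0535% and 0.0804% of the other fungus.

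**Figure D1:**
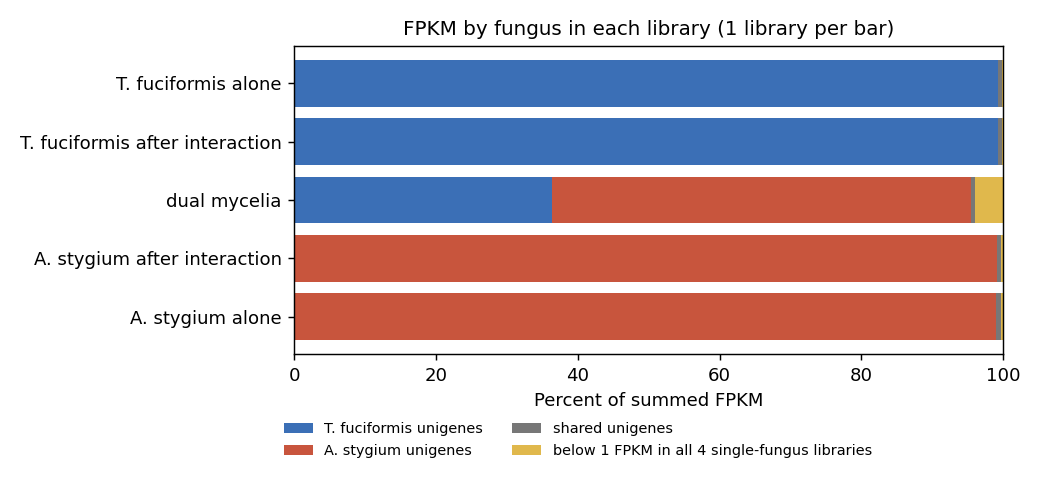
Percent of summed FPKM (x axis) held by T. fuciformis, A. stygium, shared and low unigenes in each of the 5 libraries (1 bar per library). The dual library is the only bar with large parts of both fungi, 36.4% and 59.0%.

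The comparison of T. fuciformis after interaction with T. fuciformis alone asked which of its transcripts differed once it had met A. stygium. The lists of sugar transporters and of the glyoxylate cycle and beta-oxidation of fatty acids had higher medians, and that of ribosomal proteins a slightly lower one. The riboflavin-aldehyde forming enzyme CL5907.Contig2 had 210.4 FPKM alone and 1837 FPKM after interaction, a log2 ratio of 3.09. The cytochrome P450 Unigene11669, named after DIT2, had 198 and 1024 FPKM, a log2 ratio of 2.33. The catalase-peroxidase Unigene5430, of a family that removes hydrogen peroxide, had 9.91 and 78.4 FPKM.

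Of 15354 T. fuciformis unigenes, 373 were at least 4-fold higher and 165 at least 4-fold lower after interaction, and 84.3% lay within 2-fold. The sugar transporter list had a median log2 ratio of 0.38, at percentile 100 of the random lists. Of its 87 members, 19 were at least 2-fold higher and 2 at least 2-fold lower. The member with the largest ratio was the maltose permease MAL31 (Unigene1896), with 1.16 FPKM alone and 12.5 FPKM after interaction. The most abundant, the sugar transporter STL1 (Unigene5421), went the other way, from 224 to 141 FPKM. With only members of at least 10 FPKM the list's median was 0.07, at percentile 94.4. The glyoxylate cycle and beta-oxidation list had a median of 0.64, at percentile 100, with 4 of 15 members at least 2-fold higher and 0 lower. It held the carnitine O-acetyltransferases Unigene9755, with 149 and 217 FPKM, and Unigene19018, with 7.66 and 27.4 FPKM, which pass acetyl groups between compartments. The 16 cytochrome P450 members had a median of 0.35, at percentile 99.1, but only 2 were at least 2-fold higher and 14 lay within 2-fold. In the dual library their median was -0.09, at percentile 61.9.

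The 113 ribosomal protein members had a median log2 ratio of -0.31, below all random lists, although 104 of them lay within 2-fold. The 40S protein S23 (CL318.Contig1) had 1299 FPKM alone and 1148 FPKM after interaction. The mitochondrial 54S protein L19 (Unigene168), which the search words also took, went from 53.2 to 154 FPKM. Breakdown of chitin and beta-1,3-glucan had a median of -0.26, at percentile 0.09, with 0 of 38 members at least 2-fold higher and 2 at least 2-fold lower. With contigs summed it was -0.21, at percentile 3.68, inside the band of the random lists. Its mutanase CL744.Contig2, an alpha-1,3-glucanase, had 120.0 and 53.3 FPKM. Cell wall synthesis had a median of -0.22 at percentile 1.62 (3.68 with at least 10 FPKM), heat shock proteins -0.22 at percentile 1.98 and lignin-modifying oxidases -0.33 at percentile 1.41. The 11 members of this last list are mostly contigs of a few clusters, too few to run it with contigs summed, so that it describes few genes. Among single-contig genes with the largest ratios were the aldo/keto reductase Unigene3520 (2.14 and 28.3 FPKM) and a flavonol synthase-like oxygenase, Unigene7021 (11.4 and 119 FPKM). The glycoside hydrolase/deacetylase CL993.Contig2 (1.87 and 25.9 FPKM), an alpha-glucoside transporter, CL3588.Contig2 (2.25 and 21.8 FPKM), and the thaumatin family protein CL4670.Contig1 (2.44 and 22.3 FPKM) were also higher.

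Decreases were smaller. The largest decrease was that of the amino acid transporter CL578.Contig1, from 50.5 to 10.01 FPKM, but with the contigs of its cluster summed the log2 ratio was -0.50. The phosphatase Unigene2646 went from 76.2 to 20.7 FPKM, and the glycosidase CL2550.Contig4 from 129 to 37.9 FPKM. The other 7 named decreases had log2 ratios between -1.67 and -1.42. They were the sorting proteins CL594.Contig4 and CL5809.Contig1, the amino acid transporter CL5272.Contig1, the aromatic aminotransferase CL1976.Contig1, the verprolin-related CL7427.Contig2, the GTP-binding protein CL7603.Contig2 and the lipid reductase Unigene3511. The increases of the multidrug resistance protein CL588.Contig4, listed at 0 alone, and of the DNA polymerase gamma contig CL3594.Contig1 shrank to log2 ratios of 0.40 and 0.38 with contigs summed. The counts depended on low values and on contigs. With at least 10 FPKM required, 87 unigenes were 4-fold higher and 10 lower, and with contigs summed 181 and 70 of 8930 clusters were. Assigned on the libraries grown alone, which leaves out unigenes below 1 FPKM alone and with them many increases, 88 were higher and 166 lower, so that decreases were in the majority. Over all alternatives at 4-fold the counts ran from 51 to 1012 higher and from 5 to 494 lower.

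The dual library was then compared with T. fuciformis alone. In the mixed mycelia, the oxidative stress list of T. fuciformis had a higher median after rescaling, and the ribosomal protein list a lower one. A nitroreductase and an aldehyde reductase, both contigs of clusters, were among the unigenes that were higher, and a lipid reductase was among those that were lower. Of 744 T. fuciformis contigs past 4-fold in the dual library whose clusters held other contigs, 53.5% had a cluster sum within 2-fold. Because T. fuciformis filled 36.4% of that library, its FPKM values are raised by a factor of 2.91 before the ratio is taken. The nitroreductase CL3464.Contig3 was listed at 0 alone, had 6.52 FPKM after interaction and 137 FPKM in the dual library. The chaperone HSP31 (Unigene3062), of a family linked to stress, had 2.01, 15.8 and 219 FPKM, a log2 ratio of 7.92 in the dual library. The aryl-alcohol dehydrogenase Unigene8456 had 19.7, 129 and 462 FPKM, a log2 ratio of 6.05.

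Of 14206 unigenes, 708 were at least 4-fold higher in the dual library and 506 at least 4-fold lower. The median of all was -0.17. A unigene below 1 FPKM in all 4 single-fungus libraries was assigned to neither fungus. Its increase in the dual library could not count here, while decreases could. The oxidative stress list had a median of 0.67, above all random lists, against -0.07, at percentile 48.2, after interaction. Of its 32 members in the dual library, 11 were at least 2-fold higher, 4 of these at least 4-fold. A further 21 lay within 2-fold and 0 were at least 2-fold lower. The catalase-peroxidase Unigene5430 had 55.1 FPKM, a log2 ratio of 3.93. The manganese superoxide dismutase CL2280.Contig2 had 436 FPKM alone and 197 FPKM in the dual library, a log2 ratio of 0.39 after rescaling. Also among the largest increases were the oxidoreductase Unigene14337 (2.46 and 80.0 FPKM) and the aldehyde reductase CL3847.Contig3 (1.25 and 46.1 FPKM). The remaining increases were the BCS1-like chaperone CL2569.Contig3, the arginine-rich protein Unigene1730, the Dan4p-like Unigene12355, the glycoside hydrolase family 55 protein CL4894.Contig1 and the retrotransposon protein Unigene19097. Their log2 ratios ran from 5.56 to 6.26. The transposable element list had a median of 0.40, at percentile 99.9, with 9 of 31 members at least 4-fold higher, but among members with at least 10 FPKM it was -0.13, at percentile 71.5. Sugar transporters had a median of 0.16, at percentile 99.5, with 23 of 72 members at least 2-fold higher and 6 lower. That median was -0.076 among members with at least 10 FPKM.

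The ribosomal list had a median of -0.56, below all random lists. Cell cycle and DNA replication had -0.38, at percentile 0.59, with 21 of 95 members at least 2-fold lower, and cell wall synthesis had -0.53, at percentile 2.23. Both calls were lost under alternatives. The cell cycle list came to lie inside the band of the random lists, at percentile 2.83, with at least 10 FPKM required. The cell wall list lay inside it at 4.48 with that filter, at 2.86 with a pseudocount of 0.1 and at 3.65 without rescaling. The chitin synthase 4 contig CL5188.Contig3 went from 34.4 to 4.45 FPKM, a log2 ratio of -1.36 that became -0.34 with contigs summed. Of the 10 largest decreases only the lipid reductase Unigene3511 was a single contig (11.9 and 0.31 FPKM). With contigs summed, the other 9 had log2 ratios between -1.31 and 0.90. These 9 were CL1311.Contig8, CL5370.Contig1, CL578.Contig1, CL4784.Contig1, CL6653.Contig1, CL1591.Contig1, CL1293.Contig8, CL4373.Contig4 and CL7597.Contig1. They carry names such as topoisomerase 2 and lactose permease. Of all 4-fold calls, 58.3% were increases, but 7.44% were without rescaling, when the partner's share of the reads lowers each value, with 185 higher and 2302 lower. Without rescaling the median of all was -1.42, and the oxidative stress (-0.84), transposable element (-0.97) and sugar transporter (-0.90) lists were also below 0, while their percentiles stayed at 99.6 or more. The counts were 259 and 89 with at least 10 FPKM required, 402 and 182 of 8293 clusters, and 448 and 506 when assigned on the libraries grown alone. Over all alternatives at 4-fold they ran from 185 to 886 higher and from 56 to 2302 lower.

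A. stygium after interaction was compared with A. stygium alone in the same way. The lists of cellulose breakdown and of ribosomal proteins had higher medians, and that of polyketide, nonribosomal peptide and terpene synthesis a lower one. The copper transporter-like CL1489.Contig2 had 9.58 FPKM alone and 171 FPKM after interaction, a log2 ratio of 4.03. The alkaline proteinase Unigene8818 had 3.51 and 78.0 FPKM, a log2 ratio of 4.23. The family 61 glycoside hydrolase Unigene8969, of a family that cuts crystalline cellulose by oxidation, had 1.84 and 29.9 FPKM, and pectate lyase E (Unigene14514) was listed at 0 alone and had 19.9 FPKM.

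Of 18667 unigenes, 547 were at least 4-fold higher and 569 at least 4-fold lower, with a median of all of -0.13. The cellulose list had a median log2 ratio of 0.46, above all random lists, with 28 of 77 members at least 2-fold higher, 10 of them at least 4-fold, and 4 at least 2-fold lower. Its most abundant member, the wall endoglucanase Unigene2623, had 741 FPKM alone and 598 FPKM after interaction. Hemicellulose and pectin breakdown had a median of 0.06, at percentile 98.2, with 11 of 52 members at least 2-fold higher and 37 within 2-fold. Lignin-modifying oxidases had -0.23, at percentile 37.1, and -0.02 in the dual library, at percentile 84.9. The 123 ribosomal protein members had a median of 0.25, above all random lists, and mitochondrial respiration had 0.07, at percentile 98.6. In the dual library the ribosomal list was at -0.10, at percentile 68.9. The 40S protein S23 (CL318.Contig4) had 1421 FPKM alone and 1822 FPKM after interaction. Lectins and adhesins had a median of 0.25, at percentile 98.0, over 10 members, led by the adhesin EAP1-like Unigene8882 with 121 and 630 FPKM. That median turned to -0.15 with contigs summed and to -0.37 among members with at least 10 FPKM. The metalloproteinase Unigene2612 had 39.2 and 297 FPKM.

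The polyketide, nonribosomal peptide and terpene list had a median of -0.44, below all random lists. Of its 161 members, 47 were at least 2-fold lower and 21 at least 2-fold higher. The terpene synthase Unigene9153 went from 12.2 to 2.39 FPKM. Cell cycle and DNA replication had -0.22, at percentile 1.38, and 2.82 with at least 10 FPKM required. Single-contig genes among the largest decreases were a 2-oxoglutarate-dependent dioxygenase, Unigene14536 (43.0 and 3.35 FPKM), the dienelactone hydrolase Unigene9479 (17.8 and 1.76 FPKM), the choline dehydrogenase-like Unigene263 (17.4 and 2.15 FPKM), a zinc finger protein, Unigene2484 (90.4 and 19.5 FPKM), and the epoxide hydrolase Unigene14580 (37.3 and 8.22 FPKM). The ribonuclease CL4129.Contig1 (2.10 and 94.6 FPKM), the family protein CL2330.Contig5 (0.32 and 21.5 FPKM) and the glycerol dehydrogenase CL2232.Contig1 (2.01 and 47.5 FPKM) were higher and remained over 4-fold with contigs summed.

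In 8 other contigs with the largest ratios the cluster sum moved by less than 2-fold. These were CL665.Contig8, CL515.Contig2, CL3506.Contig1 and CL1620.Contig2 among the increases and CL6935.Contig3, CL2701.Contig2, CL2192.Contig5 and CL7127.Contig5 among the decreases. With at least 10 FPKM required, 109 unigenes were 4-fold higher and 33 lower. With contigs summed, 286 and 293 of 12770 clusters were, and when assigned on the libraries grown alone 105 and 572 unigenes. Over all alternatives at 4-fold the counts ran from 67 to 1187 higher and from 24 to 1252 lower.

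The dual library compared with A. stygium alone showed higher medians for the lists of iron and siderophore genes and of sugar transporters. The lists of cellulose breakdown and of hemicellulose and pectin breakdown also had higher medians. A copper and a phosphate transporter had higher levels. The copper transporter-like CL1489.Contig2 reached 731 FPKM, a log2 ratio of 6.73 after rescaling by 1.47. The feruloyl esterase Unigene11058, of a family that frees phenolic acids from plant cell walls, had 6.25 FPKM alone, 74.2 FPKM after interaction and 408 FPKM in the dual library. The phosphate transporter PHO84 (Unigene9708) had 2.01, 36.6 and 123 FPKM. The ferric reductase CL852.Contig2, which reduces iron for uptake, had 1.64, 29.4 and 125 FPKM.

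The iron and siderophore list had a median log2 ratio of 0.87, above all random lists, against 0.06, at percentile 95.45, after interaction. Of its 29 members in the dual library, 13 were at least 2-fold higher, 6 of these at least 4-fold, and 3 at least 2-fold lower. Among the 6, CL852.Contig1, CL852.Contig2 and CL852.Contig3 belong to 1 cluster. CL1608.Contig3 and CL6386.Contig2 are also among them, while more abundant contigs of their clusters had log2 ratios between -0.43 and -0.02. Several members are contigs of the same clusters, and over 16 clusters the median was 0.75. Sugar transporters had a median of 0.61, above all random lists, against -0.07, at percentile 82.1, after interaction. In the dual library 24 of 70 members were at least 2-fold higher and 5 lower. The myo-inositol transporter Unigene13337 had 0.75 and 27.7 FPKM, and the high-affinity glucose transporter Unigene9772 had 56.5 and 126 FPKM. The cellulose list had a median of 0.48, above all random lists, with 23 of 66 members at least 2-fold higher and 7 lower. Its most abundant member, the wall endoglucanase Unigene2623, went the other way, with 741 FPKM alone and 192 FPKM in the dual library, a log2 ratio of -1.39, and the summed level of the list had a log2 ratio of -0.21. Hemicellulose and pectin breakdown had 0.31, at percentile 99.8, with 15 of 51 members at least 2-fold higher and 5 lower. Chitin and beta-1,3-glucan breakdown had 0.28, at percentile 99.0, but -0.32 among members with at least 10 FPKM and percentile 95.2 with contigs summed, and its summed level had a log2 ratio of -0.45. The alkaline proteinase Unigene8818 (196 FPKM) and the metalloproteinase Unigene2612 (385 FPKM) were higher, with log2 ratios of 6.16 and 3.83. Further large increases were those of the reverse transcriptase CL6500.Contig2, the cation channel-like Unigene14404, listed at 0 alone, the ferric/cupric reductase CL1396.Contig3, CL2330.Contig5 and CL2321.Contig1, a contig named after an outer membrane autotransporter. The last of these had a log2 ratio of 1.12 with contigs summed.

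Polyketide, nonribosomal peptide and terpene synthesis was again low, with a median of -0.38 at percentile 0.02 and 47 of 148 members at least 2-fold lower, although its summed level had a log2 ratio of 0.18. A nonribosomal peptide synthetase, CL255.Contig2, went the other way, with 12.2 FPKM alone and 186 FPKM in the dual library. Cell wall synthesis had -0.46, at percentile 0.65, and cell cycle and DNA replication -0.25, at percentile 0.04. The dioxygenase Unigene14536 had 0.26 FPKM in the dual library, a log2 ratio of -5.59. A protein named after the Asp f 2 allergen, Unigene5567, went from 80.9 to 1.79 FPKM. A membrane protein, CL1104.Contig1, had 16.3 FPKM alone and was listed at 0, and its cluster had a log2 ratio of -3.01. In the other 7 named decreases the cluster sums had log2 ratios between -1.05 and 0.36. They were CL7127.Contig4, CL184.Contig13, CL4675.Contig1, CL408.Contig5, CL6935.Contig3, CL7092.Contig1 and CL2701.Contig2. In all, 684 of 17549 unigenes were at least 4-fold higher and 874 at least 4-fold lower, with a median of all of -0.10. As for T. fuciformis, an increase of a unigene below 1 FPKM in all 4 single-fungus libraries could not count here, while decreases could. Without rescaling the median of all was -0.55, and the 2 plant cell wall lists had medians of -0.0081 and -0.22. The counts were 273 and 125 with at least 10 FPKM required, 365 and 443 of 12088 clusters, and 340 and 874 when assigned on the libraries grown alone. Over all alternatives at 4-fold they ran from 249 to 926 higher and from 91 to 1607 lower.

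**Figure D2:**
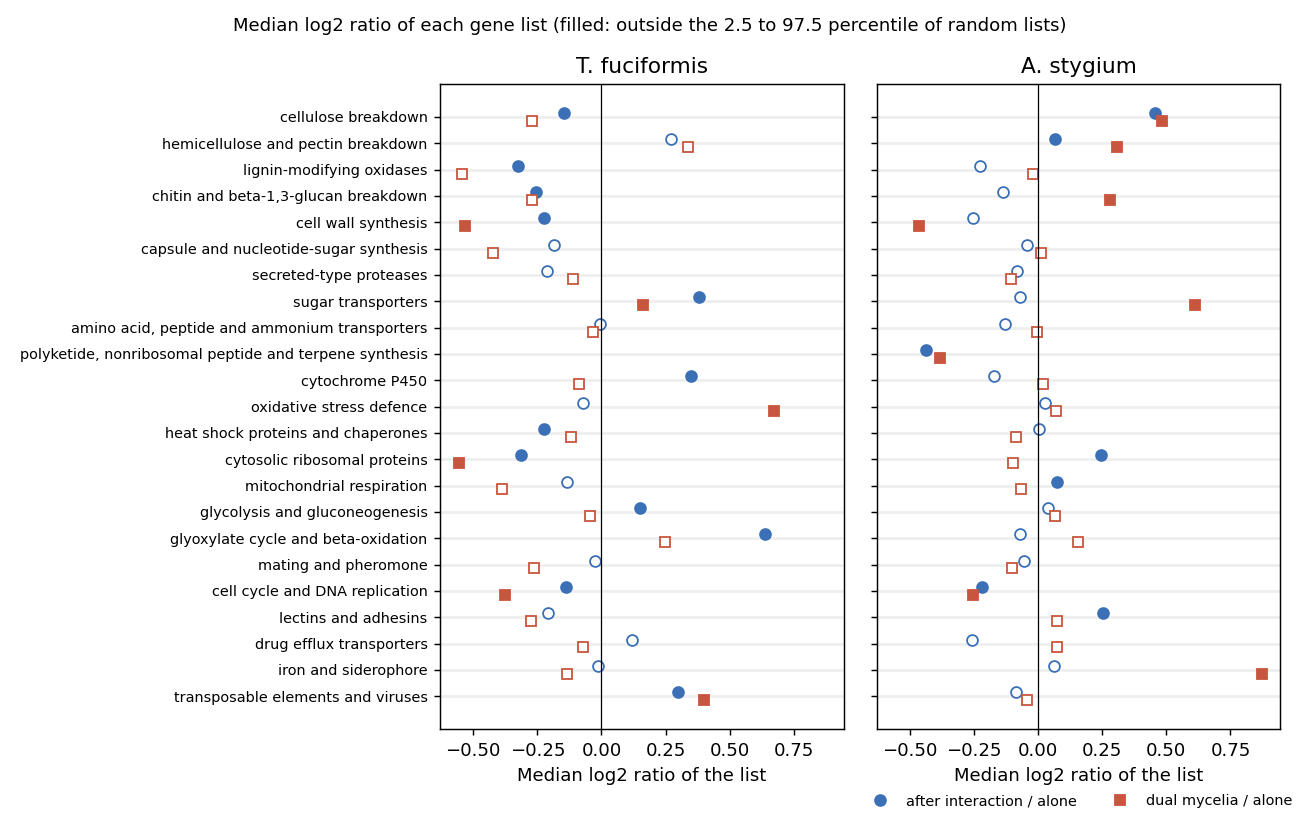
Median log2 ratio (x axis) of each gene list (y axis) in T. fuciformis and A. stygium, for the interaction library (circles) and the dual library (squares) against the same fungus alone. Filled symbols lie outside the band of the random lists. Among them is the iron and siderophore list of A. stygium in the dual library (0.87). The ribosomal protein list of T. fuciformis is filled in both libraries (-0.31 and -0.56).

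**Figure D3:**
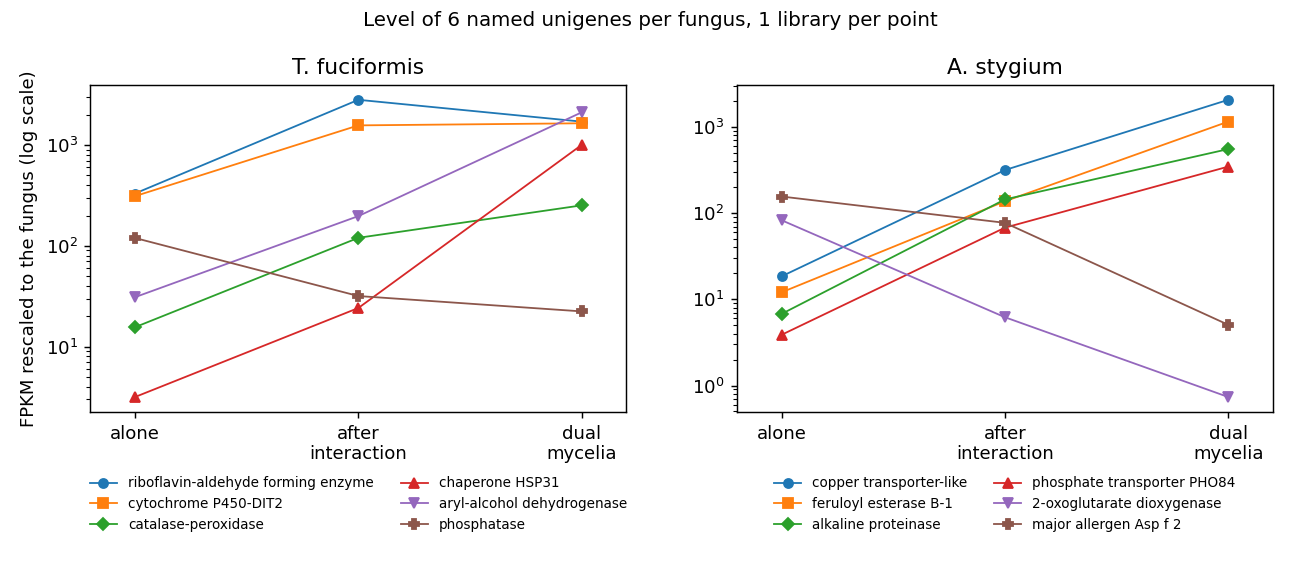
FPKM rescaled to the fungus (y axis, log scale) of 6 named unigenes per fungus in the alone, after interaction and dual libraries, with 1 library per point and lines that only join the points of a unigene. The copper transporter-like unigene of A. stygium had rescaled values of 18.5, 316 and 2067.

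The last question was whether a fungus differed from its culture alone in the same genes after interaction and in the dual library. Across T. fuciformis unigenes the 2 log2 ratios had a Pearson correlation of 0.44 over 15354 unigenes, which are not independent replicates, and 68.0% had the same sign. Of unigenes at least 4-fold higher, 133 were so in both libraries, against 18.4 for independent lists, and of those at least 4-fold lower 96, against 5.44. In A. stygium the correlation was 0.58 over 18667 unigenes and 70.2% had the same sign. There 220 unigenes were higher in both, against 20.04 for independent lists, and 316 lower in both, against 26.6. In each fungus 4 unigenes passed 4-fold in opposite directions.

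Both ratios share 1 library grown alone, which creates agreement with no effect. Unchanged groups were simulated with counting noise, and with noise raised until the product of the SDs of both ratios came close to the observed one, which takes all of the observed spread as noise. With counting noise the correlations were 0.36 in T. fuciformis and 0.45 in A. stygium, and the covariances 0.0135 and 0.0191. With the raised noise the correlations were 0.49 and 0.49, the covariances 0.442 and 0.499, and 66.3% and 65.5% of unigenes had the same sign. With noise set from the interaction ratio alone, which left both spreads below the observed ones, the covariances were 0.264 and 0.358. The observed covariance was 0.6001 in A. stygium, above all of these values. In T. fuciformis it was 0.405, above that with noise set from the interaction ratio and below that with raised noise, so its place depended on the noise assumed. The raised noise was equal in all libraries, so only the product of the SDs was matched. In T. fuciformis it gave SDs of 0.945 and 0.952, against 0.780 and 1.17 observed, so its covariance there cannot decide. Noise set from the interaction ratio put 8 unchanged T. fuciformis unigenes 4-fold higher and 4 lower in both libraries, and 23 and 21 for A. stygium. The raised noise put 42 and 59 there for T. fuciformis, and 79 and 114 for A. stygium. Independent lists are therefore not the value expected without an effect. For the ratio after interaction by itself, the raised noise put 297 unchanged T. fuciformis unigenes 4-fold higher and 266 lower. For A. stygium it put 484 and 440 there. The raised noise overstates the spread of this ratio, with SDs of 0.945 and 1.01 against 0.780 and 0.936 observed. Noise set from the interaction ratio gave SDs of 0.723 and 0.845, below the observed ones. It put 55 unchanged T. fuciformis unigenes 4-fold higher and 47 lower, and 173 and 172 for A. stygium. The observed counts were 373 and 165 for T. fuciformis, and 547 and 569 for A. stygium. The library grown alone could not be split and the noise between cultures was not measured, so part or all of the agreement may come from it.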

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

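All tests of the shared unigenes, and those of partner reads and of scaling for the iron genes, were chosen after the values had been seen. The test of contigs for the iron genes was written before its result was seen.

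Gene lists whose medians lay at opposite ends of the random lists in the 2 fungi after interaction stood out. The ribosomal protein list had a median log2 ratio of -0.31 in T. fuciformis and 0.25 in A. stygium, a difference of -0.56. In the dual library the A. stygium list was at -0.10, at percentile 68.9, so the opposite direction held after interaction and not there. The cellulose breakdown list had -0.15 and 0.46, a difference of -0.60. In T. fuciformis it was barely outside the band, at percentile 2.46, and inside it at 2.65 without rescaling. There 44 of its 48 members lay within 2-fold. In A. stygium its summed level had a log2 ratio of only 0.11. In the dual library the cellulose list had -0.27 in T. fuciformis, at percentile 12.1, and 0.48 in A. stygium, above all random lists. With at least 10 FPKM required, the T. fuciformis dual median was -0.71, at percentile 0.23, over 19 members. The summed levels in the dual library had log2 ratios of -0.85 in T. fuciformis and -0.21 in A. stygium. The differences themselves were not tested, since each fungus had 1 library per condition. The T. fuciformis culture grown alone was older than that of A. stygium, and the T. fuciformis cellulose list moved to percentile 18.8 with contigs summed.

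Signal also appeared in unigenes that belong to neither fungus by the 10-fold rule. Of the 516 shared unigenes, 321 have a nucleotide hit in Cryptococcus neoformans with an e-value below 1e-100. They held 0.439% of the FPKM of A. stygium alone, an ascomycete culture in which T. fuciformis unigenes held 0.0804%. Their summed FPKM was 2041 in T. fuciformis alone, 2219 in T. fuciformis after interaction, 2372 in the dual library, 2170 in A. stygium after interaction and 2301 in A. stygium alone. Much of these sums came from 2 unigenes named after the pheromone alpha, Unigene11813 and Unigene13283. They had 602 and 546 FPKM in T. fuciformis alone, and 645 and 632 FPKM in A. stygium alone. T. fuciformis reads in the A. stygium culture are argued against. The 1188 other transcripts at 100 FPKM or more in T. fuciformis alone, however assigned, had a median of 0.000553 of that level in A. stygium alone. A foreign fungus growing in cultures of only 1 species could not be seen here, since the 10-fold rule would assign its unigenes to that species. One growing in some cultures of both is argued against, because the highest library had 1.16 times the lowest. That ratio rests largely on 2 of the 321 unigenes. A source common to all 5 libraries, such as RNA added during library preparation or sequencing, fitted: 92.6% of the 54 more abundant ones lay within 2-fold of their mean in all 5 libraries. Reads of each fungus on sequence conserved between them may also contribute and were not tested, nor was any biological explanation.

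A second group was seen only in the dual library. There, 488 unigenes had at least 10 FPKM and stayed below 1 FPKM in all 4 single-fungus libraries. They held 2.36% of the FPKM of that library, with a median of 17.96 FPKM and a highest value of 653 FPKM. Only 13.7% had an Nr hit, against 95.9% of assigned unigenes as abundant, and of the 67 with a hit 40 were nearest to Tremellomycetes and 3 to Xylariales. Whether they are genes expressed only in the mixed mycelia was not tested.

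The higher iron and siderophore genes of A. stygium in the dual library were weighed as well. A scaling error is argued against, because the list's median lay 0.97 above that of all A. stygium unigenes. Reads moving between contigs are argued against as the whole cause, because the median was 0.75 over 16 clusters. Partner reads stay open. T. fuciformis alone had 0.000546 of the list's summed FPKM in the dual library, but the 10-fold rule that assigned these unigenes allows at most 0.0670. Growth stage, medium and the contact itself stay open too, and no biological explanation was tested.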

How the results depend on the processing

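Summing contigs, and lists without rescaling, were alternatives chosen after the data were seen. No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. Shares of each fungus kept within 1 percentage point under the 3 other assignments, and the correlations between ratios within 0.1 under both alternatives. Counts of 4-fold unigenes, by contrast, depended on low values. Counts follow as higher and lower, for T. fuciformis after interaction, T. fuciformis dual, A. stygium after interaction and A. stygium dual. With a pseudocount of 5 they were 51 and 5, 359 and 56, 67 and 24, 249 and 91. With at least 10 FPKM required they were 87 and 10, 259 and 89, 109 and 33, 273 and 125, as fewer unigenes entered. At 2-fold they were 1598 and 807, 1794 and 1878, 1847 and 2109, 2080 and 2592. Without rescaling they were 194 and 74, 185 and 2302, 223 and 159, 249 and 467. In that setting the pseudocount of 1 is added to smaller values and so weighs more. After interaction the rescaling factors were only 0.975 and 0.960, so the lower counts there cannot be credited to scaling between libraries alone. With contigs summed they were 181 and 70, 402 and 182, 286 and 293, 365 and 443, as fewer items entered. With a pseudocount of 0.1 they were 1012 and 494 and, for A. stygium, 1187 and 1252 after interaction, and the lower counts in the dual library were 1097 and 1607. Assignment on the libraries grown alone, which drops unigenes absent there, gave 88 and 166, 448 and 506, 105 and 572, 340 and 874. Other counts stayed within 1.5 times, including those with no filter, median-ratio scaling and assignment at 100-fold or 3-fold. After interaction, leaving out the filter could not change the counts, since assignment already required 1 FPKM in 1 of the same libraries. Median-ratio scaling moved the median of all in T. fuciformis dual from -0.17 to -0.03 and in A. stygium after interaction from -0.13 to -0.02.

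Of 90 list medians, 33 lay outside the band. Direction and side of the band were both kept by 88 with a pseudocount of 0.1, 70 with median-ratio scaling, 65 without rescaling, 64 of the 86 that the filter at 10 FPKM could be run on, and 71 of the 88 that had enough clusters with contigs summed, in the same order by 32, 32, 23, 23 and 28 of those outside the band. Of lists inside the band 0, 18, 14, 3 and 9 changed sign, many of them near 0, and 1, 1, 2, 9 and 5 moved outside. Among the 9 that the filter moved outside were 3 breakdown lists of T. fuciformis dual. They were cellulose (-0.71), chitin and glucan (-0.63) and lignin-modifying oxidases (-0.71). Of lists outside the band, the filter turned 4 around, to -0.076 for sugar transporters and -0.13 for transposable elements of T. fuciformis dual, -0.37 for lectins of A. stygium after interaction and -0.32 for chitin and glucan breakdown of A. stygium dual. Summing contigs turned the lectins around, to -0.15. Without rescaling, which shifts each value in the dual library, 6 turned. These were sugar transporters (-0.90), oxidative stress (-0.84) and transposable elements (-0.97) of T. fuciformis, and breakdown of cellulose (-0.0081), of hemicellulose and pectin (-0.22) and of chitin and glucan (-0.20) of A. stygium. Of 234 named ratios, 101 passed 4-fold. With contigs summed 33 no longer did and 6 turned around, to 0.90 for CL1591.Contig1, 0.024 for CL4373.Contig4, -0.74 for CL515.Contig2, -0.17 for CL1620.Contig2, 0.36 for CL184.Contig13 and -0.75 for CL3925.Contig1, since their clusters' other contigs moved otherwise. With a pseudocount of 5, 13 no longer passed. The cause of the other differences was not tested. Depth limits unigenes near 1 FPKM, whose counting error is 22.4%.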

Other observations

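The tests of contigs moving within clusters were written before their results were seen, except that of contigs listed at 0, which was chosen after.

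Hydrophobins, small secreted proteins that coat fungal walls, had 3 members, all of them assigned to A. stygium. The precursor Unigene10417, named here after its values were seen, had 12969 FPKM alone, 13132 FPKM after interaction and 6631 FPKM in the dual library, a log2 ratio of -0.42 there after rescaling, since A. stygium held 59.0% of that library. It had 6.36 and 8.98 FPKM in the T. fuciformis libraries. The polyketide, nonribosomal peptide and terpene list had 0 members in T. fuciformis. In T. fuciformis after interaction, glycolysis had a median log2 ratio of 0.15 at percentile 99.4, transposable elements 0.30 at percentile 99.0 and cell cycle genes -0.14 at percentile 1.5. With at least 10 FPKM required the transposable elements were at 0.06, at percentile 92.6.

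Other lists stayed inside the band in their main comparisons. For T. fuciformis after interaction and in the dual library, medians were -0.19 and -0.42 for capsule and nucleotide sugars, -0.21 and -0.11 for proteases, and -0.01 and -0.03 for transporters of amino acids, peptides and ammonium. They were -0.02 and -0.26 for mating and pheromones and 0.12 and -0.07 for drug efflux. For A. stygium in the same order they were -0.04 and 0.01 for capsule and nucleotide sugars, -0.08 and -0.11 for proteases, and -0.13 and -0.01 for transporters of amino acids, peptides and ammonium. They were -0.06 and -0.10 for mating and pheromones and -0.26 and 0.07 for drug efflux. Several of these medians near 0 changed sign under alternatives. The protease list of A. stygium after interaction moved outside the band with contigs summed, at 0.0097 and percentile 98.9. The capsule list of T. fuciformis in the dual library, at percentile 3.42, was inside the band by little. It lay outside under each of the 5 alternatives run on lists, at percentile 0.01 with at least 10 FPKM required, 0.43 with contigs summed, 1.14 without rescaling, 1.53 with a pseudocount of 0.1 and 2.48 with median-ratio scaling.

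Shared unigenes named after the mating pheromone alpha had nearly equal levels in the 5 libraries, from 601.6 to 696 FPKM for Unigene11813 and from 546 to 664 FPKM for Unigene13283, both named after their values were seen. They are among the 321 shared unigenes with a Cryptococcus neoformans nucleotide hit. A further 38 shared unigenes with a nearest hit in Beauveria bassiana summed to between 64.9 and 73.0 FPKM.

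Many 4-fold ratios belonged to contigs of clusters with other contigs, and reads moving between these contigs could produce them. In T. fuciformis the other contigs moved the opposite way in 39.8% of 314 such contigs after interaction and in 26.7% of 735 in the dual library. In A. stygium these shares were 54.4% of 562 and 42.2% of 855. Such shifts may account for some of these ratios, but the shares were neither high nor low enough to decide for the whole. The share to be found if the other contigs moved independently was not measured, so these values alone do not show such shifts. The cluster sum stayed within 2-fold in 77.4%, 53.5%, 77.8% and 59.4% of all 4-fold contigs of such clusters in the same order, which were 314, 744, 562 and 864, since those whose other contigs stayed below 1 FPKM count here too, and in 63.6% of the 44 contigs listed at 0 in 1 library and at 10 FPKM or more in the other. It passed 4-fold in the same direction in 39, 209, 37 and 176 of them. A change of isoform or allele would give the same picture and was not tested.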
